A study of Mus musculus with 18 samples.

How the data were processed

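RNA was profiled on 1-colour Affymetrix gene arrays from 18 samples of mouse dendritic cells or sorted CD11b+ or CD103+ cells, 9 from mice with a CD11c-Cre driven BRAFV600E allele (BRAF below) and 9 from Cre-negative littermate controls (WT below). CD11c-Cre acts in cells expressing the integrin CD11c, which dendritic cells carry. The 8 groups were genotype by population: bone marrow derived dendritic cells (BMDC, sorted as live CD11c+CD11b+ cells; 3 arrays per genotype, marrow from mice of 5 weeks), and liver CD11b+, lung CD11b+ and lung CD103+ cells (2 arrays per genotype each, mice of 14 weeks). Per the labels' protocols, total RNA was extracted with Trizol and labelled with biotin. No further gate is stated for the organ populations. The labels number the replicates but do not say that they came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

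The deposited values are array intensity on a linear scale, with array medians from 93.7 to 113.2 and a highest value of 20362. How the authors made and normalized the intensity values before deposit is not given in the sources used here. Everything after that was computed here: log2 was taken with no added constant and the arrays were not normalized again. The number of arrays limits the precision.

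Of 24922 probe sets, 21425 had 1 gene symbol, 1399 had several and 2098 were not listed in the gene table used and are unnamed here. The Entrez number matched the RefSeq gene table for 21347 probe sets, and 0 symbols changed. Only probe sets with 1 symbol were used, which cover 19752 genes; for the 921 genes with over 1 probe set, the one with the highest mean was taken. A gene was tested when its log2 value lay above the array's 30th percentile on at least 2 arrays, which left 15365 genes.

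Models were fitted with limma 3.58.1 in R 4.3.3, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for tables and plots. A mean per group was fitted over all 18 arrays (10 residual degrees of freedom, prior 4.8), since 6 of the 8 groups hold only 2 arrays and share 1 estimate of the spread per gene. Contrasts were BRAF minus WT in each population, the unweighted mean of these 4, their differences (a moderated F test and pairwise contrasts), lung CD103+ minus lung CD11b+, and liver minus lung CD11b+. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over the genes tested, and a gene was called under 0.05. Errors after a log2 fold change are standard errors; errors after a group mean are SD.

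The design, the alternatives, the rule for naming genes and 43 gene lists were set before the data were examined. The lists hold 931 entries, of which 837 matched a gene; 42 were tested and the list of sex-linked genes was kept for checks. Lists were tested against all other genes with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation; limma's fry was run as an alternative, which tests whether a list's genes move, on balance, 1 way and does not compare the list with other genes. Named genes were Braf, Itgax, Ccr7 and Bcl2l1; in each genotype contrast the 10 called genes with the largest change each way whose genotypes do not overlap (in the mean effect, with the same sign in all 4 populations); up to 4 members with the smallest p per list that passed; the 6 largest each way in the population contrasts; and the 6 smallest p of the F test. The text gives a selection of the list members so named; 2 immunoglobulin segments were passed over in liver. Fabp7, Arg1 and other genes are also compared across populations where 1 contrast named them.

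The fits were tested on simulated data over 15365 genes. A log2 change of 1 was recovered for 57% of the changed genes in BMDC, 22% in liver, 19% in lung CD11b+, 24% in lung CD103+ cells and 96% in the mean effect, and a change of 2 for 96%, 92%, 93%, 91% and 100%. False calls made up 5.6%, 8.1%, 5.9%, 0% and 6.7% of the calls in the same order. The simulated noise was independent and normal, with the same spread on every array. The real arrays differed in spread (limma's array weights ran from 0.11 to 6.02), so these rates may not carry over to them.

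Replicate numbers were checked for pairing by correlating the deviations of same-numbered arrays from their group means. In lung, CD103+ and CD11b+ arrays of 1 number deviated together (r = 0.159 in WT and 0.22 in BRAF, across genes), so a fit with the number as a block was run beside the main one; with 2 arrays per group both pairs of a genotype give the same r.

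Alternatives were quantile normalization, centring on array medians, no filter or a filter at the 50th percentile, the mean of a gene's probe sets, trend and robust eBayes, array weights (limma's gene-by-gene method, since the default stopped before it converged), fits of only the groups compared, replicate blocks, and leaving out each array in turn. Where that left 1 array in a group, the lone array was assumed to vary like the other groups. Added after seeing the data were a fit without the 2 arrays of narrowest spread and a fit with the mean of 3 Y-linked genes as a covariate.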

Results

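The data set holds 18 arrays in 8 groups, 9 from BRAF and 9 from WT mice, over 4 populations of mouse myeloid cells: BMDC (3 arrays per genotype) and liver CD11b+, lung CD11b+ and lung CD103+ cells (2 arrays per genotype each). The series concerns the effect of active RAF, MEK and ERK signalling on the migration of dendritic cells, as in Langerhans cell histiocytosis (LCH), a disease in which such cells form lesions. The interquartile range of log2 values was 1.9 on BRAF BMDC replicate 2 and 1.92 on WT liver CD11b+ replicate 3, and 2.41 to 2.99 on the other 16 arrays.

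Braf itself, the gene carrying the transgenic allele, was tested first. Its log2 signal was 8.76 ± 0.11 in WT and 8.8 ± 0.29 in BRAF BMDC (SD, n = 3 each). The log2 difference was 0.04 ± 0.25 in BMDC, 0.32 ± 0.3 in liver, -0.03 ± 0.3 in lung CD11b+ and -0.12 ± 0.3 in lung CD103+ cells, and none passed the test (adjusted p = 0.945, 0.608, 1 and 1). The sign in BMDC and in lung CD11b+ cells turned under other scalings. The array does not tell the mutant allele from the normal one, so this checks only total Braf signal. Itgax, which encodes CD11c, and Bcl2l1, which encodes the survival protein BCL-XL, were not called in any population. The mean log2 differences over the 4 populations were -0.07 ± 0.2 and 0.11 ± 0.13.

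Ccr7, the chemokine receptor that guides mature dendritic cells to lymph nodes, was lower in BRAF than in WT cells of every population. In BMDC it fell by 1.93 ± 0.28 on the log2 scale, from 9.49 ± 0.31 to 7.56 ± 0.44 (SD, n = 3 each; adjusted p = 0.00464). In lung CD11b+ cells it fell by 3.11 ± 0.34, from 10.6 ± 0.13 to 7.49 ± 0.18 (SD, n = 2 each; adjusted p = 0.00141), and in lung CD103+ cells by 2.03 ± 0.34 (adjusted p = 0.0421). The liver difference of -1.22 ± 0.34 did not pass (adjusted p = 0.171). The lung CD103+ call was lost without BRAF replicate 1 (-1.59, adjusted p = 0.671) and without WT replicate 3 (-1.7, adjusted p = 0.351). It was also lost in a fit of only the groups compared (adjusted p = 0.535), and after quantile normalization (0.0781), median centring (0.0567) and array weights (0.0588). The calls in BMDC and lung CD11b+ cells held without each array in turn. A fit with the replicate number as a block ended the BMDC call, although same-numbered BMDC arrays did not all deviate together. A difference of the Ccr7 effect between populations was not called (adjusted p of the F test = 0.396).

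**Figure D1:**
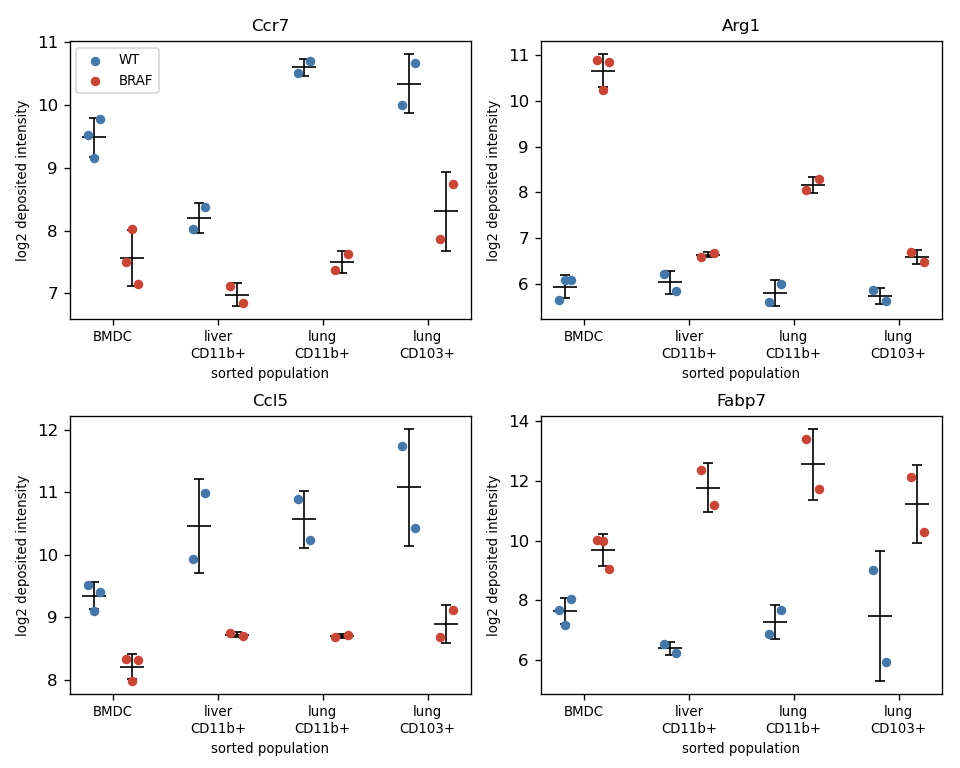
Log2 deposited intensity (vertical axis) of Ccr7, Arg1, Ccl5 and Fabp7 on each array, by sorted population (horizontal axis). Points are arrays, WT in blue and BRAF in red, and black bars are group means with SD. Every BRAF array lies below every WT array of its population for Ccr7 and Ccl5, and above it for Arg1 and Fabp7.

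In BMDC, the largest called increases in BRAF cells were in Ccl7, Arg1, Mmp13 and Serpinb2, and all 18 genes of the cholesterol synthesis list were lower. Ccl7 and Ccl2, chemokines that attract monocytes, rose by 5.04 ± 0.36 and 3.98 ± 0.46 on the log2 scale (adjusted p = 3.54e-06 and 0.000705; n = 3 each). Arg1, which breaks down arginine, rose by 4.73 ± 0.21, the matrix protease gene Mmp13 by 4.11 ± 0.53, and the serpin genes Serpinb2 and Serpinb10 by 4.09 ± 0.23 and 3.85 ± 0.4. Further called increases were Plcb4 (3.15 ± 0.24), Ch25h, which makes 25-hydroxycholesterol (3.19 ± 0.64), Ifi213 (2.81 ± 0.51), Ifitm6 (2.71 ± 0.44) and the neutrophil chemokine Cxcl3 (1.61 ± 0.25). Beside Ccr7, the nuclear receptor gene Nr4a3 fell by 2.29 ± 0.29, Cyp4a12a by 2 ± 0.28, the chemokine gene Cxcl16 by 1.83 ± 0.3, Slc27a3 by 1.78 ± 0.22 and Vat1l by 1.67 ± 0.27.

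The cholesterol synthesis list had a median of -1.61 in BRAF BMDC, and 10 genes were called lower over all genes and 18 adjusted over the list alone (camera adjusted p = 2.24e-31; adjusted p = 0.0555 with an estimated correlation). They included Hmgcs1 (-1.94 ± 0.3), Cyp51 (-1.96 ± 0.39), Hsd17b7 (-1.86 ± 0.26), Nsdhl (-1.79 ± 0.32) and Sc5d (-1.62 ± 0.26). Of 25 interferon response genes 4 were called higher over all genes and 13 adjusted over the list alone, with a median of 0.79 (camera adjusted p = 7.38e-16; adjusted p = 0.117 with an estimated correlation). Oas2 rose by 1.92 ± 0.27, Ifit1 by 1.83 ± 0.27, Ifit3 by 1.58 ± 0.3 and Ifit2 by 1.5 ± 0.3. The calls of Ifit2 and Cyp51 were lost without any 1 of the 6 arrays (adjusted p up to 0.247 and 0.178), and that of Ifit3 without each array but BRAF replicate 2 (up to 0.18). Of 29 ERK target genes 2 were called, Etv1 (1.68 ± 0.31) and Fosl1 (0.91 ± 0.18), and 4 adjusted over the list alone, with a median of 0.31 (camera adjusted p = 3.8e-06; adjusted p = 0.0555 with an estimated correlation). Both calls were lost without each array but BRAF replicate 2 (adjusted p up to 0.139 and 0.218). Hbegf at 1.28 ± 0.34 and Spry1 at 0.59 ± 0.18 did not pass over all genes. The mature dendritic cell list, named for Ccr7, had 1 of 28 genes called lower, 9 adjusted over the list alone, and a median of -0.36 (camera adjusted p = 0.000183; adjusted p = 0.117 with an estimated correlation). That median was -0.17 without BRAF replicate 2. Pdcd1lg2 at -1.98 ± 0.42 and Ccl22 at -2.43 ± 0.56 did not pass (adjusted p = 0.0513 and 0.0872). Chemokine genes went both ways, with 4 called higher and 1 lower, and 9 and 3 adjusted over the list alone (median 0.34, camera adjusted p = 5.91e-05; adjusted p = 0.333 with an estimated correlation). The inflammatory cytokine list had a median of 0.26, with 0 called, and the matrix protease list of 0.28, with 1 called (adjusted p = 0.375 each with an estimated correlation). The T cell marker list had a median of 0.28 beside these (adjusted p = 0.552 with an estimated correlation).

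The limma test called 80 of 15365 genes in BMDC, 51 higher and 29 lower, and 1022 had an unadjusted p under 0.05, against 768 in any contrast if no gene differed. The count was 31 without BRAF replicate 1, 24, 20 and 30 without WT replicate 1, 2 and 3, 103 without BRAF replicate 2 and 54 without BRAF replicate 3. It was 1657 with array weights and 44 in a fit of only the BMDC groups. Of 28 named called genes 14 kept the call without each array in turn, among them Arg1, Ccl2, Ccl7, Ccr7, Ifit1, Mmp13, Nr4a3, Oas2, Plcb4 and both serpins. Of the 6 such fits, 6 ended the call of Cyp51 and Ifit2, 5 that of Ch25h, Etv1, Fosl1, Ifi213 and Ifit3, 4 that of Ifitm6, 3 that of Cxcl16, Nsdhl, Sc5d and Vat1l, 2 that of Cxcl3 and 1 that of Hmgcs1.

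In liver CD11b+ cells, Fabp7, which encodes a fatty acid binding protein, rose by 5.38 ± 0.83, from 6.4 ± 0.23 to 11.78 ± 0.81 (SD, n = 2 each; adjusted p = 0.0214). Lcn2, an iron-siderophore binding protein of innate defence, rose by 3.56 ± 0.65, Ifitm1 by 2.15 ± 0.28 and the membrane protein gene Emp1 by 1.76 ± 0.24. Further called increases were in Styx, Nxpe5, Tpmt, Trdmt1, Clybl and Btf3l4, from 1.74 to 2.21 (Styx, 1.39 without WT replicate 3). Retnla, a marker of alternatively activated macrophages, fell by 3.99 ± 0.67, the interferon-inducible genes Ifi205 and Ifi203 by 2.07 ± 0.39 and 1.12 ± 0.21, Rtp4 by 1.79 ± 0.34, the eosinophil chemokine Ccl24 by 1.68 ± 0.29, and the mast cell protease gene Cpa3 by 1.66 ± 0.26. Tnfrsf17, the plasma cell receptor BCMA, fell by 1.88 ± 0.35, Ptprb by 1.71 ± 0.28 and Slc46a3 by 1.67 ± 0.32.

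Of 25 interferon response genes 24 had a negative log2 fold change in liver, with a median of -1.03, and 0 were called over all genes and 15 adjusted over the list alone (camera adjusted p = 1.02e-13; adjusted p = 0.243 with an estimated correlation). The median was -0.66 without WT replicate 1. Ifit3 stood at -1.59 ± 0.37, Oas2 at -1.39 ± 0.33 and Cxcl10 at -1.48 ± 0.41. The cholesterol list had a median of -0.86, with 0 called and 1 adjusted over the list alone (adjusted p = 0.521 with an estimated correlation). That median was -0.48 without BRAF replicate 2. Members included Cyp51 at -1.73 ± 0.48. The mature dendritic cell list had a median of -0.28, with 0 called and 4 adjusted over the list alone (adjusted p = 0.243 with an estimated correlation). It was -0.44 without BRAF replicate 2 and -0.46 without WT replicate 3, and its call was lost without WT replicate 1 (adjusted p = 0.0796). Ccl17 stood at -3.54 ± 0.71 and Ccl5 at -1.74 ± 0.39. Markers of other cells moved with these: B cell markers had a median of -0.36, T cell markers of -0.48 and NK cell markers of -0.62 (adjusted p = 0.552 each with an estimated correlation), and mast cell, basophil and eosinophil markers of -0.62 (adjusted p = 0.243). The B cell call was lost without WT replicate 1 (adjusted p = 0.0682). The NK cell median was -0.33 without BRAF replicate 3 and -0.39 without WT replicate 1, and its call was lost (adjusted p = 0.31 and 0.219). Neutrophil markers had a median of 0.5 and did not pass (camera adjusted p = 0.112), with list means of 7.07 and 7.73 on the BRAF and 6.71 and 6.49 on the WT arrays. Stress and immediate early genes had a median of -0.58, with 0 called (adjusted p = 0.521 with an estimated correlation). That median was -0.27 without BRAF replicate 3, -1.01 without WT replicate 3 and -0.05 without WT replicate 1, which ended the call (adjusted p = 0.515). Jchain, a plasma cell gene, stood at -5.1 ± 1.38 without passing.

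The test called 33 genes in liver, 22 higher and 11 lower, with 2170 at an unadjusted p under 0.05. Quantile normalization gave 31 higher and 28 lower, array weights 1 gene, a fit of only the liver groups 7 and the mean of the probe sets 18. The count was 358 without BRAF replicate 2, 72 without WT replicate 1, 15 without WT replicate 3 and 23 without BRAF replicate 3, and of 19 named called genes only Emp1 kept its call without each array in turn.

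In lung CD11b+ cells the largest increase was again in Fabp7, by 5.28 ± 0.83, from 7.27 ± 0.57 to 12.55 ± 1.19 (SD, n = 2 each; adjusted p = 0.0123). The scavenger receptor gene Colec12 rose by 3.18 ± 0.39, Slc7a2, a transporter of cationic amino acids, by 2.98 ± 0.59, Raet1d, a ligand of the activating receptor NKG2D, by 2.87 ± 0.41, Arg1 by 2.37 ± 0.26, the protease gene Mmp19 by 2.35 ± 0.45 and Plcb4 by 2 ± 0.29. Beside Ccr7, the C-type lectin gene Cd209f fell by 4.37 ± 0.53, the tight junction gene Cldn1 by 3.64 ± 0.66, Apol7c by 3.08 ± 0.53, P3h2 by 2.65 ± 0.37 and Fscn1, the actin bundling protein of mature dendritic cells, by 2.95 ± 0.36. Grasp (-3.11 ± 0.61), Slc15a2 (-2.44 ± 0.4), Adam23 (-2.38 ± 0.34), Cd209b (-2.27 ± 0.45), Adam19 (-1.84 ± 0.27) and Mmp25 (-1.51 ± 0.29) also fell. Cd209b stood at -1.3 without BRAF replicate 1.

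The mature dendritic cell list had a median of -0.59, with 23 of 28 genes negative, 2 called lower and 11 adjusted over the list alone (camera adjusted p = 6.88e-13; adjusted p = 0.0124 with an estimated correlation). Ccl5 at -1.86 ± 0.39 and Relb at -1.05 ± 0.24 did not pass over all genes. Genes common to conventional dendritic cells had a median of -1.06, with 20 of 22 negative, 1 called and 12 adjusted over the list alone (camera adjusted p = 2.78e-16; adjusted p = 0.0424 with an estimated correlation). Members included Kit at -1.57 ± 0.35 and Runx3 at -1.49 ± 0.33. Stress and immediate early genes had a median of -1.12, with 0 called and 14 adjusted over the list alone (camera adjusted p = 6.93e-17; adjusted p = 0.116 with an estimated correlation). Members included Fosb at -1.87 ± 0.42 and Junb at -1.28 ± 0.3. The cholesterol list had a median of -0.69 (adjusted p = 0.474 with an estimated correlation), which was -0.09 without BRAF replicate 1 and -1.11 without BRAF replicate 2.

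Macrophage markers moved with these groups: the Kupffer cell list had a median of 0.96, which was -0.08 without BRAF replicate 1 and 1.62 without BRAF replicate 2. The alveolar macrophage list had a median of 0.66, which was 1.41 and 0.12 without them in turn (adjusted p = 0.474 and 0.456 with an estimated correlation). Cd5l, a Kupffer cell gene, read 10.33 on BRAF replicate 1 and 5.2 on BRAF replicate 2. The B cell list had a median of -0.72 (adjusted p = 0.474 with an estimated correlation), which was -0.21 without WT replicate 1 and -1.35 without WT replicate 3.

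The test called 52 genes in lung CD11b+ cells, 11 higher and 41 lower, with 1031 at an unadjusted p under 0.05. The count was 149 without the 2 arrays of narrowest spread and 369 with array weights. It was 97 without BRAF replicate 2, 16 without BRAF replicate 1, 18 without WT replicate 3 and 7 without WT replicate 1, and of 22 named called genes Arg1, Ccr7, Cd209f, Colec12 and Fscn1 kept the call without each array in turn.

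In lung CD103+ cells, BRAF cells had more transcript of the macrophage elastase gene Mmp12, which rose by 4.41 ± 0.58, from 7.2 ± 1.3 to 11.61 ± 0.64 (SD, n = 2 each; adjusted p = 0.00703). The Fc receptor gene Fcgr4 rose by 3.71 ± 0.64, the chemokine gene Ccl9 by 2.95 ± 0.35, Colec12 by 2.87 ± 0.39, Hpgd, which inactivates prostaglandins, by 2.78 ± 0.34, Il1rn, which encodes the interleukin-1 receptor antagonist, by 2.33 ± 0.4 and Emp1 by 1.52 ± 0.24. Fcgr4 stood at 2.38 without WT replicate 3. Beside Ccr7, Gnao1 fell by 2.51 ± 0.38, Cd207, which encodes the lectin langerin, by 2.4 ± 0.36, Ct55 by 2.11 ± 0.26, Pir by 1.85 ± 0.29 and Vipr1 by 1.49 ± 0.25.

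Of 26 macrophage genes 25 had a positive log2 fold change, with a median of 1.73, and 1 was called over all genes and 16 adjusted over the list alone (camera adjusted p = 4.84e-40; adjusted p = 0.0244 with an estimated correlation). The median was 0.85 without BRAF replicate 1. Adgre1, which encodes F4/80, stood at 2.12 ± 0.41 and the mannose receptor gene Mrc1 at 3.48 ± 0.75 without passing over all genes, and at 1.29 and 1.87 without WT replicate 3. The interferon list had a median of 0.82, with 0 called and 9 adjusted over the list alone, the complement and scavenger list 0.95, with 0 and 9, and the monocyte list 0.6, with 0 and 5. Msr1 of the scavenger list stood at 2.77 ± 0.52 and Fn1 of the monocyte list at 3.95 ± 0.72 (2.48 without WT replicate 3). The interferon median was 0.51 without BRAF replicate 2 and the monocyte median 0.34 without WT replicate 3. All of these lists had an adjusted p of 0.0244 with an estimated correlation. ERK targets had a median of 0.28, with 1 called and 2 adjusted over the list alone, and the mature dendritic cell list -0.43, with 1 called and 6 adjusted over the list alone (both adjusted p = 0.0244 with an estimated correlation). Ier3 stood at 1.39 ± 0.31, Ccl5 at -2.18 ± 0.39 and Fscn1 at -1.99 ± 0.36. Other markers moved with these: the lung epithelium list had a median of 0.38 and the hepatocyte list of 0.59 (adjusted p = 0.161 and 0.262 with an estimated correlation), which were 0.05 and -0.06 without BRAF replicate 1, on which Alb read 10.98. The hepatocyte median was 1.29 without BRAF replicate 2. Neutrophil markers had a median of 0.11 (adjusted p = 0.17 with an estimated correlation), which was 0.26 without WT replicate 1, and the call was lost without BRAF replicate 1 (0.03) and WT replicate 3 (0.04), at an adjusted p up to 0.214. The list of conventional dendritic cell type 2 genes had a median of -0.35 while camera gave it upward (adjusted p = 0.495 with an estimated correlation).

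The test called 13 genes in lung CD103+ cells, 7 higher and 6 lower, with 655 at an unadjusted p under 0.05, fewer than the 768 if no gene differed. The count was 3 without BRAF replicate 1, 90 without BRAF replicate 2, 96 without WT replicate 1 and 14 without WT replicate 3, and 0 when only the 2 groups compared were fitted. It was 21 without the 2 arrays of narrowest spread, 24 with the Y-linked covariate and 23 with trend and robust eBayes. Of 13 named called genes only Ccl9 kept its call without each array in turn.

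**Figure D2:**
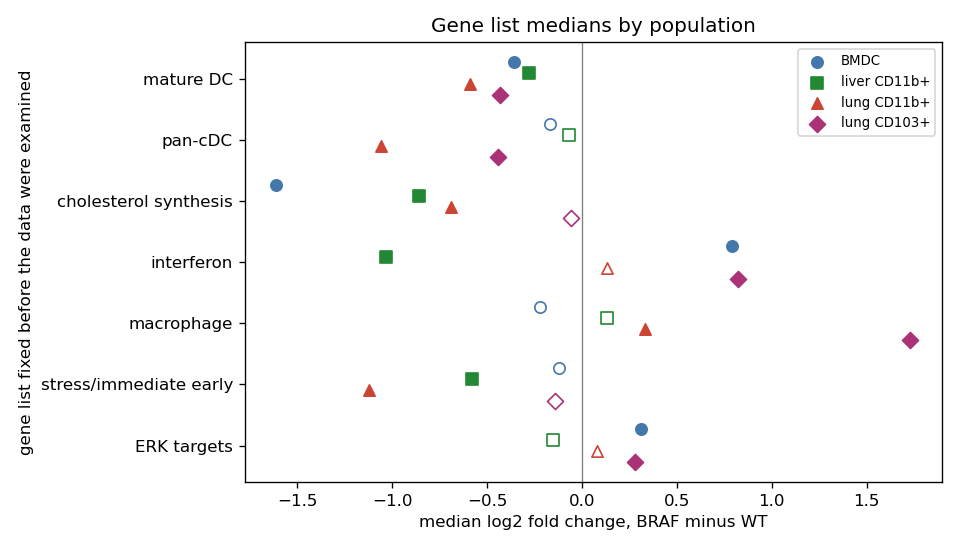
Median log2 fold change, BRAF minus WT (horizontal axis), of 7 gene lists (vertical axis) in each population. Marker shapes are populations, and filled markers passed camera at the preset correlation. The mature dendritic cell list lies below 0 in all 4 populations, from -0.59 to -0.28, and the interferon list lies at 0.79 in BMDC and at -1.03 in liver.

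The 4 genotype effects were averaged, which does not require that each population shows the effect. All arrays were treated as independent here, although same-numbered lung arrays deviated together (r = 0.159 in WT and 0.22 in BRAF). The errors of the mean effect may therefore be understated. Ccr7 fell by 2.07 ± 0.16 (adjusted p = 8.79e-06; 9 arrays per genotype), as did Ccl22 by 2.06 ± 0.33 and Ccl17 by 2.02 ± 0.34, chemokines of mature dendritic cells, Ccl5 by 1.73 ± 0.19 and Fscn1 by 1.72 ± 0.17. Fabp7 rose by 4.11 ± 0.4, Mmp8 by 2.27 ± 0.36, Arg1 by 2.14 ± 0.12, Raet1d by 2.07 ± 0.2, Trem1, an amplifier of myeloid inflammation, by 2 ± 0.28 and Plcb4 by 1.84 ± 0.14. Cldn1 fell by 1.97 ± 0.32, Apol7c by 1.87 ± 0.26, Nr4a3 by 1.4 ± 0.17, H2-M2 by 1.38 ± 0.26 and Il12rb2 by 1.2 ± 0.23. Fcrl5, Fcgr4, Fn1 and Mmp12 rose, by values from 1.64 to 1.79.

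The mature dendritic cell list fell in the mean effect, with 23 of 28 genes negative, a median of -0.46, 7 called and 18 adjusted over the list alone (camera adjusted p = 1.04e-16; adjusted p = 0.00413 with an estimated correlation). Stress and immediate early genes moved beside it, with 18 of 19 negative and a median of -0.5. Of these 1 was called, Dnajb1 at -0.88 ± 0.18, and 12 were lower and 1 higher adjusted over the list alone (camera adjusted p = 8.46e-13; adjusted p = 0.124 with an estimated correlation). All 18 cholesterol genes were negative, with a median of -0.73, 5 called and 15 adjusted over the list alone (adjusted p = 0.0836 with an estimated correlation). In lung CD103+ cells alone the list had a median of -0.06, with 10 of 18 negative and 0 called (camera adjusted p = 0.511), and its mean difference between BMDC and these cells was -1.5 (camera adjusted p = 1.78e-25; adjusted p = 0.106 with an estimated correlation). Called members included Cyp51 (-1.2 ± 0.23), Hmgcs1 (-0.94 ± 0.18) and Mvd (-0.67 ± 0.14). Genes of conventional dendritic cells had a median of -0.4, with 3 called and 9 adjusted over the list alone (adjusted p = 0.0836 with an estimated correlation). The called members were Cbfa2t3 (-0.91 ± 0.16), Kit (-0.82 ± 0.17) and Jaml (-1.06 ± 0.22), and 11 of 18 fits without 1 array ended the calls of Kit and Jaml. The median was -1.06 in lung CD11b+ and -0.44 in lung CD103+ cells, against -0.17 in BMDC and -0.07 in liver, where the list was not called (camera adjusted p = 0.0734 and 0.102). The mean difference from lung CD11b+ cells was 0.71 for BMDC and 0.81 for liver (camera adjusted p = 1.14e-08 and 0.000386; adjusted p = 0.178 and 0.682 with an estimated correlation). Of the matrix protease list 4 were called higher and 1 lower, with 9 and 2 adjusted over the list alone (median 0.26; adjusted p = 0.0836 with an estimated correlation). Members included Mmp19 at 1.2 ± 0.21 and Mmp25 at -0.85 ± 0.14. Macrophage genes had a median of 0.57, with 1 called and 8 adjusted over the list alone (adjusted p = 0.205 with an estimated correlation), and the median was 0.36 without BRAF lung CD103+ replicate 1. Their median was 1.73 in lung CD103+ cells, against 0.33 in lung CD11b+, 0.13 in liver and -0.22 in BMDC, the last 2 not called (camera adjusted p = 0.481 and 0.434). The lung CD11b+ change did not hold with an estimated correlation. The mean difference from lung CD103+ cells was -1.85 for BMDC and -1.46 for liver (camera adjusted p = 2.62e-24 and 5.72e-12; adjusted p = 0.152 and 0.209 with an estimated correlation). ERK targets had a median of 0.17, with 2 called and 2 adjusted over the list alone (adjusted p = 0.112 with an estimated correlation). The called members were Il1rn (0.92 ± 0.19) and Etv1 (0.86 ± 0.18), and 13 and 11 of 18 fits without 1 array ended these calls. The ERK target median was 0.31 in BMDC and 0.28 in lung CD103+ cells, but 0.08 in lung CD11b+ and -0.15 in liver cells, neither of them called (camera adjusted p = 0.603 and 0.189). It was -0.07 and 0.19 in lung CD11b+ cells without BRAF replicates 1 and 2. In liver it was 0 without WT replicate 1, and the list was called lower without BRAF replicate 2 (-0.17, adjusted p = 0.0261) and WT replicate 3 (-0.07, 0.038). BMDC and liver cells differed by 0.39 in the list mean (camera adjusted p = 0.00105; adjusted p = 0.219 with an estimated correlation).

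The test called 152 genes, 75 higher and 77 lower, with 1440 at an unadjusted p under 0.05. The count was 324 without the 2 arrays of narrowest spread and 270 after quantile normalization. Single arrays moved it between 67, without WT lung CD11b+ replicate 1, and 280, without BRAF BMDC replicate 2, with 75 without BRAF lung CD103+ replicate 1, 75, 80 and 96 without WT BMDC replicates 1 to 3, 98 without BRAF BMDC replicate 1, 78 without WT liver replicate 1, 80 without WT lung CD11b+ replicate 3 and 236 without BRAF lung CD103+ replicate 2. Of 36 named called genes 18 kept the call without each array in turn, among them Ccr7, Ccl5, Ccl17, Ccl22, Fscn1, Arg1, Fabp7 and Plcb4. The call was lost without at least 1 array for Fcgr4, Fcrl5, Fn1, H2-M2, Il12rb2, Dnajb1, Cyp51, Hmgcs1, Mvd, Kit, Jaml, Il1rn and Etv1, with an adjusted p of at most 0.112.

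Whether the genotype effect differed between populations was tested directly. Arg1 differed (adjusted p of the F test = 5.45e-05), at 4.73 in BMDC, 2.37 in lung CD11b+, 0.86 in lung CD103+ and 0.61 in liver cells, as did Serpinb2 (5.45e-05), Ccl7 (0.00141) and Serpinb10 (0.00543), all highest in BMDC. Rtp4 stood at 2.08 in BMDC and -1.79 in liver (0.00969), and Ifi203 at 1.08 and -1.12 (0.0105). The F test called 19 genes, with 1398 at an unadjusted p under 0.05. The count was 5 without BRAF BMDC replicate 1 or WT BMDC replicate 1 or 2, 6 without WT BMDC replicate 3 and 10 without BRAF BMDC replicate 3. It was 9 and 8 without WT lung CD11b+ replicates 1 and 3, 34 without BRAF BMDC replicate 2, and 68, 47 and 88 without replicate 2 of BRAF lung CD11b+, lung CD103+ and liver cells. Without WT lung CD103+ replicate 1 it was 50. It was 249 with array weights, 36 without the 2 arrays of narrowest spread and 11 with median centring. Pairwise, BMDC differed from liver in 21 genes, from lung CD11b+ cells in 20 and from lung CD103+ cells in 8, while limma called 0 among the organ populations, with 1392, 1435 and 372 at an unadjusted p under 0.05. The interferon list differed by 1.78 on average between BMDC and liver (camera adjusted p = 9.75e-19; adjusted p = 0.219 with an estimated correlation).

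Genes called in the same direction in a pair of populations numbered 6 for BMDC and lung CD11b+ cells (3 higher and 3 lower, against 0.037 and 0.077 for independent lists): Arg1, Plcb4, Raet1d, Ccr7, Nr4a3 and Slc27a3. BMDC and liver cells shared 2 (Emp1 and Plcb4), and 3 were called in opposite directions there (Ifi203, Ifi205 and Rtp4). BMDC and lung CD103+ cells shared 2 (Ccr7 and Emp1), liver and lung CD11b+ cells 3 (Fabp7, Plcb4 and Slc46a3), liver and lung CD103+ cells 1 (Emp1) and the lung populations 3 (Ccr7, Colec12 and Vipr1), against at most 0.073 in a direction for independent lists. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.434 (rho 0.363) between lung CD11b+ and lung CD103+ cells, 0.267 (rho 0.313) between BMDC and lung CD11b+ cells and -0.332 (rho -0.458) between BMDC and liver cells. It was 0.135 (rho 0.153) between BMDC and lung CD103+ cells, 0.111 (rho -0.05) between liver and lung CD11b+ cells and 0.01 (rho -0.072) between liver and lung CD103+ cells, so that r and rho differed in sign in the last 2 pairs. After quantile normalization r was -0.178 between BMDC and liver and 0.214 between liver and lung CD11b+ cells. The 2 arrays of narrowest spread are BRAF BMDC replicate 2 and WT liver replicate 3, which enter these effects with opposite signs. Part of the negative correlation between BMDC and liver may come from them. Same-numbered lung arrays deviated together, which can raise the correlation and the overlap between the lung populations.

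**Figure D3:**
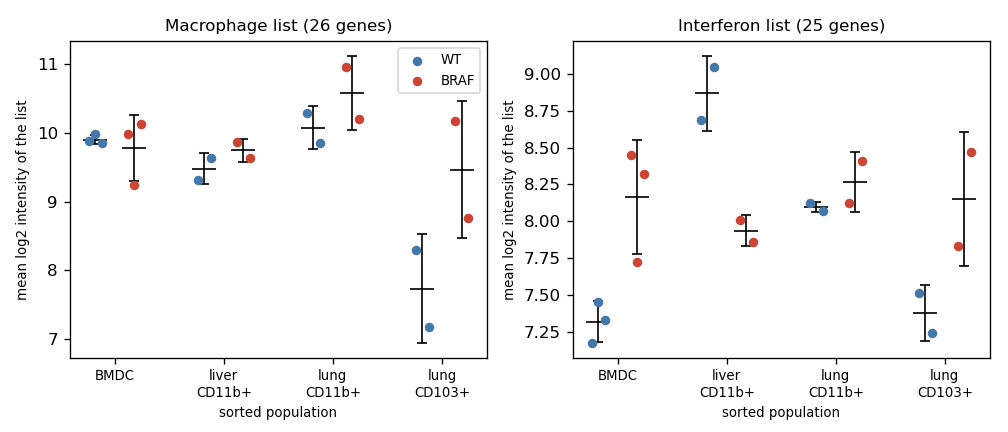
Mean log2 intensity (vertical axis) of the macrophage list (26 genes) and the interferon list (25 genes) on each array, by sorted population (horizontal axis). Points are arrays, WT in blue and BRAF in red, and black bars are group means with SD. Macrophage means in lung CD103+ cells were 8.3 and 7.17 on the WT and 10.17 and 8.76 on the BRAF arrays, and interferon means in liver were 8.69 and 9.05 on the WT and 8.01 and 7.86 on the BRAF arrays.

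Lung CD103+ cells were set against lung CD11b+ cells over both genotypes to describe the sorted populations. Gpr33 was higher in CD103+ cells by 5.68 ± 0.19, Itgae, which encodes CD103, by 5.14 ± 0.26, Xcr1, the chemokine receptor of type 1 conventional dendritic cells, by 5.12 ± 0.26, and Naalad2, Gcsam and Gpr141b by values from 4.22 to 5.11 (4 arrays per population). Called lower were Retnla (-4.75 ± 0.47), Ptgs2, the inducible cyclooxygenase (-4.23 ± 0.46), Itgam, which encodes CD11b (-3.28 ± 0.29), and Fcrls, Emb, Pla2g7 and Ifitm6 (-3.88 to -3.37). Of 22 type 1 conventional dendritic cell genes 18 were called higher and 21 adjusted over the list alone (adjusted p = 3.55e-05 with an estimated correlation). They included Septin3 (4.18 ± 0.17) and Snx22 (3.1 ± 0.15). Of 18 type 2 genes 11 were called lower and 14 adjusted over the list alone (adjusted p = 0.0415 with an estimated correlation). These included Cd209a (-2.53 ± 0.35) and Clec4a2 (-2.45 ± 0.29). Of 26 macrophage genes 17 were called lower and 23 adjusted over the list alone (adjusted p = 0.0568 with an estimated correlation). The test called 867 genes, 386 higher and 481 lower, with 1357 called without the 2 arrays of narrowest spread.

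Liver CD11b+ cells had more transcript of Cd34 (2.03 ± 0.23), the histone genes H2bc8, H3c4 and H1f3 (1.55 to 2.02), Id3 (1.81 ± 0.26) and Ifitm1 (1.5 ± 0.2) than lung CD11b+ cells, over both genotypes (4 arrays per organ). They had less of Sftpc, the surfactant protein gene of lung epithelium (-3.1 ± 0.4), Il1a (-3.03 ± 0.54), Retnla (-2.92 ± 0.47), Folr2 (-2.91 ± 0.48) and P3h2 (-2.85 ± 0.26). The mature dendritic cell list was lower in liver, with 28 of 28 genes negative, a median of -0.62, 4 called and 14 adjusted over the list alone (adjusted p = 0.0231 with an estimated correlation). At the preset correlation, camera called 19 of 42 lists lower in liver and 5 higher, so this list did not move alone. The test called 325 genes, 31 higher and 294 lower, with 62 higher and 244 lower after quantile normalization and 109 in a fit of only the groups compared. Without WT liver replicate 1 it called 1220, without WT liver replicate 3 81, without WT lung replicates 1 and 3 90 and 134, without BRAF lung replicates 1 and 2 169 and 215, and without BRAF liver replicate 3 207. Of 16 named called genes 11 kept the call without each array in turn, and that of Il1a was lost in 2 of these fits (adjusted p up to 0.0679).

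Over all 42 lists, the calls that held with an estimated correlation numbered 0 in BMDC and in liver, 2 in lung CD11b+ cells, 12 in lung CD103+ cells, 1 in the mean effect, 4 in the lung population contrast and 1 in the organ contrast. By fry, which asks whether a list's genes move, on balance, 1 way, the numbers past the threshold were 5, 0, 3, 0, 5, 16 and 7 in the order BMDC, liver, lung CD11b+, lung CD103+, mean, lung populations and organs.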

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

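The tests of explanations and the counts over other splits of the arrays in this part were chosen after the results were seen; the test of differences between populations was planned.

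The genotype effect differed between populations for 15 named genes by the limma F test. Adjusted p was 5.45e-05 for Arg1 and Serpinb2, 0.00141 for Ccl7, 0.00543 for Serpinb10 and 0.0393 for Mmp13, each highest in BMDC. The interferon-inducible genes Rtp4 (0.00969), Ifi203 (0.0105) and Ifi205 (0.0272) were called higher in BRAF BMDC and lower in BRAF liver cells. Oas2 (0.0272) and Ifit1 and Ifit3 (0.0429 each) were called higher in BMDC and stood at -1.39, -1.03 and -1.59 in liver without passing. Cd209f and Adam23 were lowest in lung CD11b+ cells (0.0302 and 0.0429) and Ct55 was lowest in lung CD103+ cells (0.0302). Colec12 (0.0302) stood at 3.18 in lung CD11b+ and 2.87 in lung CD103+ cells, against 0.4 in BMDC and -0.02 in liver. The F test does not say which populations differ. By limma's pairwise contrasts, Cd209f, Adam23 and Colec12 differed only between BMDC and lung CD11b+ cells (adjusted p = 0.023, 0.023 and 0.0488). Ct55 differed only between BMDC and lung CD103+ cells (0.019), and Mmp13 did not differ between these 2 (0.486).

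Among 2720 tested probe sets with several or no gene symbols, which the comparisons did not use, limma called 7 in BMDC, 4 in liver, 5 in lung CD11b+ and 2 in lung CD103+ cells, 11 in the mean effect, 58 between the lung populations, 15 between the organs and 3 by the F test.

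Macrophage genes were higher in BRAF lung CD103+ cells, with a median of 1.73 that was 0.85 without BRAF replicate 1, an array that correlated at 0.97 with BRAF lung CD11b+ replicate 1 and at 0.962 with the other array of its group. If other cells of every kind had entered the BRAF sorts alike, lymphoid markers would have risen too. The mean of 43 lymphoid genes was 7.65 and 6.29 on the WT and 7.12 and 6.51 on the BRAF arrays. The macrophage list mean minus that mean was 0.65 and 0.88 on the WT and 3.05 and 2.25 on the BRAF arrays. This gap of 1.37, against a larger range within a genotype of 0.81, argues only against entry of every kind alike. An impure sort need not let in all kinds alike. Of 11 lists of other cells only 3, those of T, B and NK cells, moved apart from the macrophage list by more than the larger range within a genotype, and 2 had higher means on both BRAF than on both WT arrays, neutrophils (6.73 and 6.51 against 6.41 and 6.04) and erythroid cells (6.34 and 6.43 against 6.29 and 5.99), while lung epithelium (7.83 and 6.9 against 7.04 and 6.57) and hepatocytes (7.68 and 6.06 against 6.26 and 6.09) overlapped, so entry of some kinds of cell stays open. Macrophages caught in the sort, which gated on CD103, may account for the pattern. The alveolar macrophage list means were 8.39 and 6.57 on the WT and 8.86 and 8.3 on the BRAF arrays. The lowest BRAF array stood at -0.09 from the highest WT array, so the genotypes overlapped, and 2 arrays each cannot decide. The Kupffer cell list means were 6.73 and 6.04 on the WT and 7.51 and 6.78 on the BRAF arrays. Abundant macrophage genes read 12.26 and 10.24 (Chil3), 12.07 and 9.89 (C1qb) on the BRAF arrays, against 9.57 and 4.13, and 9.64 and 7.23, on the WT arrays, and a change of gene expression within BRAF CD103+ cells stays open as well.

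The interferon list had a median of 0.79 in BRAF BMDC and -1.03 in BRAF liver cells (adjusted p = 0.117 and 0.243 with an estimated correlation, and 0.219 for the difference), and the liver median was -0.66 without WT replicate 1. The 2 arrays of narrowest spread do not account for it, since the mean difference of the list was 1.78 with them and 2.19 without them. The sex of the animals was tested with a Y-linked covariate, which left a liver median of -0.98 with an upper quartile of -0.71. All BMDC arrays had high Y-linked signal, so the covariate does not part sex from population in the difference. The BRAF liver CD11b+ replicate 3 array correlated at 0.961 to 0.969 with 5 BMDC arrays, against 0.955 with the other array of its group. It also correlated at 0.968 with WT lung CD11b+ replicate 3 and 0.963 with BRAF lung CD11b+ replicate 2, so this was not particular to BMDC. Its Y-linked mean of 4.31 stood at -3.54 from the lowest BMDC array (7.85, with a range of the BMDC arrays of 0.71). That argues against a large share of material from these BMDC, and the liver median was -0.81 without this array. Medians of B, T and NK cell markers in liver were -0.36, -0.48 and -0.62, so another make-up of the BRAF liver sorts may contribute and stays open beside a different response of the 2 populations to mutant BRAF, which remains a hypothesis.

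Ccr7 was lower in BRAF cells. In BMDC the stress and immediate early list had a median of -0.12, with quartiles of -0.26 and 0.06, against -1.93 ± 0.28 for Ccr7. This argues against handling stress that moves these genes in BMDC, but does not test stress that lowers Ccr7 without them. In lung CD11b+ cells that list had a median of -1.12 (-0.58 in liver and -0.5 in the mean effect) and moved with Ccr7, so stress and genotype cannot be told apart there. In lung CD103+ cells, where Ccr7 was also called lower, the list means were 9.58 and 9.42 on the WT and 9.26 and 9.41 on the BRAF arrays. A lower share of mature cells in the BRAF sorts may also contribute, since 23 of 28 genes of the mature dendritic cell list were negative in the mean effect, which lower expression per cell gives as well. The genotype itself is the biological explanation the design names and stays open.

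Other splits of the arrays were counted. For BMDC, 10 splits are too few for a share under 0.05: the real split gave 80 genes and 17 lists, the highest other 0 genes and 12 lists, and 1 split of 10 reached each real value. For the mean effect, 1 of 100 splits within populations gave as many as 152 genes (highest other 62) and 4 of 100 gave as many as 27 lists (highest other 27). These splits part same-numbered arrays of different organs, which can share structure, and so may understate chance. Of 60 splits that keep organ arrays in groups, 1 gave as many genes (highest other 74) and 2 as many lists (highest other 27). In BRAF these groups joined liver replicate 3 to lung replicates 1, whose numbers differ. They also joined liver replicate 2 to lung replicates 2, whose sex-linked signals differ (Xist 11.11 against 5.2 and 5.4). Both highest other counts came from splits with the real genotype grouping of all organ arrays, which has few alternatives. The share is under 0.05 only because BMDC splits are counted in. It does not exclude chance for the organ arrays alone. In fits of 2 groups without genotype, 1 of 35 splits gave as many as 35 genes between the organs (highest other 5, the split by genotype). This is a share under 0.05 only if the arrays are independent. The WT liver and lung CD11b+ arrays numbered 3 both read Xist and Y-linked genes. They may share animals, which these splits do not allow for. Between the lung populations, where same-numbered arrays pair, 8 splits part all 4 pairs, too few for a share under 0.05: the real split gave 601 genes and the highest other 0. Of all 35 splits of these arrays, of which the others keep some pairs together, 1 gave as many (highest other 2).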

How the results depend on the processing

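The fit without the 2 arrays of narrowest spread and the Y-linked covariate were chosen after seeing the data. Over named genes, settings other than leaving out arrays gave the same call in 1960 cases, a lost call in 187, a gained one in 48 and a turned sign in 8; with 1 array left out these were 1204, 327, 18 and 21, and no called gene changed sign. For a subset of the lists, settings other than leaving out arrays gave the same outcome, called or not, in 432 cases. In this subset the call was lost in 78, of which 40 were with an estimated correlation and 38 with fry. With 1 array left out, further list calls of the subset were lost and the direction turned in 4 cases. The subset leaves out other called lists, some of which lost the call elsewhere. Over all 42 lists, camera without the 2 arrays of narrowest spread kept 13 calls in BMDC (10 up and 7 down with all arrays). It kept 16 in liver (3 and 15), 15 in lung CD11b+ (6 and 10), 24 in lung CD103+ cells (19 and 5) and 22 in the mean effect (16 and 11). Except where stated, the cause was not tested. Most groups hold 2 arrays, which limits the precision.

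Counts moved by over 1.5 times as follows. Without the 2 narrow arrays they were 149 in lung CD11b+, 21 in lung CD103+ cells, 324 in the mean effect, 1357 between lung populations and 36 by the F test. Array weights gave 1657 in BMDC, 1 in liver, 369 in lung CD11b+ cells and 249 by the F test. Fitting only the groups compared, with fewer residual degrees of freedom, gave 44 in BMDC, 7 in liver, 0 in lung CD103+ cells and 109 between the organs. Quantile normalization gave 59 in liver and 270 in the mean effect, and changed the correlation of effects to -0.178 between BMDC and liver and 0.214 between liver and lung CD11b+ cells. Centring on medians gave 11 by the F test, the mean of probe sets 18 in liver, and in lung CD103+ cells the Y-linked covariate 24 and trend with robust eBayes 23. The lung CD103+ call of Ccr7 was lost with array weights and in the fit of only the groups compared (-2.03 each), and with median centring and quantile normalization (-2 each), at an adjusted p from 0.0567 to 0.535.

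In BMDC the same-numbered arrays did not deviate together (r = 0.469, -0.231 and -0.399), and the replicate block gave 14 genes, 11 of them shared. In lung, where the numbers pair, the blocked fit gave 1049 genes, 731 shared. The BMDC block also ended the call of Ccr7 (-1.93, adjusted p = 0.14). A random replicate block gave 31, 51 and 13 genes in liver, lung CD11b+ and lung CD103+ cells, 200 in the mean effect, 259 between organs and 16 by the F test.

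Leaving out single arrays gave counts of 20 to 103 in BMDC, 15 to 358 in liver, 7 to 97 in lung CD11b+, 3 to 96 in lung CD103+ cells, 67 to 280 in the mean effect, 580 to 898 between lung populations, 81 to 1220 between organs and 5 to 88 by the F test. Without single arrays Ccr7 ranged from -2.48 to -1.59 in lung CD103+ cells, where 2 arrays decided the call. Signs turned only for uncalled genes: Braf ranged from -0.1 to 0.19 in BMDC, -0.3 to 0.24 in lung CD11b+, -0.48 to 0.24 in lung CD103+ cells and -0.04 to 0.14 in the mean; Itgax from -0.66 to 0.1, -0.51 to 0.33 (liver), -0.16 to 0.33, -0.06 to 0.32 and -0.17 to 0.06; Bcl2l1 in liver from -0.2 to 0.17. List medians that turned were cell cycle in liver (-0.47 to 2.15), hepatocyte in lung CD103+ cells (-0.06 to 1.29), and ERK targets (-0.07 to 0.19) and Kupffer cell genes (-0.08 to 1.62) in lung CD11b+ cells.

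Other settings turned the sign of uncalled genes: Braf to -0.04 in BMDC with median centring, and to 0.03 with the Y-linked covariate and 0.1 with quantile normalization in lung CD11b+ cells; Itgax to 0.1 in BMDC without the 2 arrays and 0.03 in the mean with array weights; and Bcl2l1 in liver to 0.17 without the 2 arrays, 0.01 with the covariate and 0.05 with median centring.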

Other observations

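The values in this part were chosen after the data were seen, except the list tests, which were planned. Of 21 genes of the glycolysis list 2 were called in the mean effect: Egln3, an oxygen-sensing hydroxylase, rose by 0.82 ± 0.16 and Bnip3, a mitophagy receptor, by 0.84 ± 0.18, and 7 and 13 of 18 fits without 1 array ended these calls (adjusted p up to 0.0825 and 0.123). Over the list alone 3 were higher and 1 lower after adjustment (adjusted p = 0.511 with an estimated correlation), and the list's call was lost without BRAF BMDC replicate 3 (adjusted p = 0.0572) and WT liver replicate 3 (0.055). Of the osteoclast list Ctsk, the bone-degrading cathepsin K, rose by 2.38 ± 0.45 and Acp5, which encodes the phosphatase TRAP, by 1.17 ± 0.23 (2 of 15 called, 5 adjusted over the list alone; adjusted p = 0.127 with an estimated correlation), and 3 and 9 of 18 such fits ended the calls (adjusted p up to 0.0642 and 0.0853). Of 22 genes known from LCH lesions 3 were called higher, and 5 higher and 1 lower adjusted over the list alone. The median was 0.08 (camera adjusted p = 0.124 with an estimated correlation), and 0.04 without BRAF BMDC replicate 3. The 3 called were Ctsk, Acp5 and Mmp12. Ctsk and Acp5 are also the 2 osteoclast calls, so these lists do not count separate genes. In BRAF BMDC all 12 MHC class II genes had a negative log2 fold change, with a median of -0.63, 0 called over all genes and 2 adjusted over the list alone. Of 27 oxidative phosphorylation genes 25 were negative, with a median of -0.51, 0 called over all genes and 0 adjusted over the list alone. Both lists lost the call with an estimated correlation (adjusted p = 0.375 each). The MHC class II median was -0.31 without BRAF replicate 2.

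Cell cycle genes had a positive log2 fold change in BRAF liver cells for 31 of 31 genes, with a median of 0.82, 0 called over all genes and 0 adjusted over the list alone (adjusted p = 0.629 with an estimated correlation), and the median was -0.47 without BRAF replicate 3 and 2.15 without BRAF replicate 2. The list mean was 9.91 on BRAF liver replicate 3, 7.36 on BRAF liver replicate 2 and 7.67 and 7.99 on the WT liver arrays.

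Sex-linked genes did not follow genotype but differed between BMDC and most organ arrays. Differences of the genotype effect between BMDC and organ cells cannot be fully told apart from sex, or from age (5 against 14 weeks). All BMDC arrays had a high mean of 3 Y-linked genes (7.85 to 8.56) and low Xist (5.08 to 6.08). The WT organ arrays numbered 3 read both Xist and Y-linked genes: 10.33 and 6.31 in liver, 11.67 and 7.21 in lung CD11b+ and 11.71 and 7.24 in lung CD103+ cells. Both BRAF lung arrays numbered 2 had low Xist (5.2 and 5.4) with a high Y-linked mean (8.35 and 8.45), and the remaining organ arrays had Xist from 11.11 to 12.29.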
